A study of Homo sapiens with 4 samples.

How the data were processed

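Single-cell RNA libraries from 4 human breast cancer xenografts were made on the 10x Genomics Chromium system after depletion of mouse cells, per the labels' protocols. The 4 deposited tables hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, as the authors gave them, with no normalization. The human genome build was GRCh38, per the submitters' processing notes. The aligner, the counting program, the annotation release and the authors' cell filters were not given in the sources used here. Whole numbers, 16-base barcodes and column totals that differed between cells were checked in every table. The tables listed 17734 and 19065 genes for estradiol replicates 1 and 2, and 20313 and 17451 for placebo replicates 1 and 2. Of 22585 genes in any table, 14760 stood in all 4. Few listed genes were seen in under 3 cells of their table (33 and 176 under estradiol, 455 and 117 under placebo), so a gene absent from a table was not read as a count of 0, and comparisons between libraries used the genes listed in all 4.

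Each library came from 1 xenograft line grown in immunodeficient mice, with estradiol or placebo given in its treatment field, while the text on the series design named no treatment. Treatment and line differed together, and the lines of a treatment served as replicates (2 per treatment). Estradiol replicate 1 was deposited earlier than the other libraries and in another format. Library preparation dates were not in the labels, so a batch difference of that library cannot be told apart from its line. For 1 library the sample title and the xenograft field named different lines, and the treatment field was used as given. Cells with at least 1000 UMIs and at most 20% of UMIs from mitochondrially encoded genes were kept, 5431 of 6009. This removed 301 cells for low UMIs and 284 for mitochondrial share, 7 of them for both. Scrublet called 13 cells as doublets, too few to be a working doublet filter at these cell numbers, so doublets were not removed, and a run without the top 5% of cells by UMIs was added. XIST and Y-linked genes were left out of every table. Gene types and chromosomes came from GENCODE release 29, which matched between 80.8% and 84.9% of the listed gene names.

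Kept cells gave 37003150 UMIs for estradiol replicate 1 and 93395657 for estradiol replicate 2, and 49538335 and 26023990 for placebo replicates 1 and 2. A gene with 0 UMIs in the smallest library had an upper limit of 0.115 CPM (UMIs per 1e+06 UMIs of the library), from 3 counts of the total. A share near 50% had a 95% interval of about 3.52 percentage points to either side in that library. Intervals are exact (Clopper-Pearson binomial, or Poisson for ratios of counts), and they and the limits cover counting error only.

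UMIs were summed per library, and estradiol and placebo libraries were compared by the edgeR 4.0.16 quasi-likelihood test (TMM factors, filterByExpr, robust fit) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. For KRT5 and for ESR1, a cell with at least 1 UMI of the gene was positive. Each cell of the smaller class was matched within its library to the cell of the other class with the nearest total UMIs, and the summed classes were compared with library as a block. Cells were not used as replicates. The class gene itself was not tested. The class-by-treatment interaction was fitted on the same KRT5 sums. A total of 1313 KRT5 pairs and 325 ESR1 pairs entered. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, so single values between treatments are given without a p.

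The samples, comparisons, gene lists and markers were fixed before the data were examined. So were the alternative settings, except those named below as chosen after seeing the data. Of 26 lists, 21 had at least 5 tested members and were tested by camera in limma 3.58.1 with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The named genes are those past the threshold with the 8 largest changes each way, mean CPM of at least 20 and the same direction in every library pair (for treatment, no overlap between groups). To these come ESR1, PGR, GREB1, TFF1, KRT8, KRT18, KRT5, KRT14, KRT17 and MKI67 where tested, and the 3 members with the smallest p in each list that camera called. Clone-style names were passed over. PGR and TFF1 were not in all 4 tables and were not tested.

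Shares of cells with a UMI were taken after thinning each cell to 1900 UMIs and also unthinned, with cells below that depth left out. For each library, the 6 genes with the highest fold over the next library were taken among genes at 50 CPM or more. Each library was clustered separately in scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5). A cluster was named after a cell type only where at least 3 of that type's fixed markers stood at least 1 log2 unit higher than in the library's other cells, and ties were left unnamed. A class of cells with at most 0.2% of UMIs from long non-coding RNA genes (MALAT1 and NEAT1 left out) was defined after the data were seen, and the remaining cells are called human-profile cells.

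Alternatives covered DESeq2 1.42.0 size factors and test, limma on mean CPM per cell, no filter on low counts, other cell filters, doublet calls, thinned sums, cycling cells, a class threshold of 2 UMIs, unmatched cells, no block, and each library left out in turn. Counts simulated from the fitted edgeR model, with 50 genes of mean CPM of at least 20 changed at each of 2, 4, 16 and 64-fold, were tested the same way. For treatment, edgeR recovered 0%, 0%, 28% and 88% of them, and DESeq2 0%, 16%, 80% and 100%, while DESeq2 also called 84 unchanged genes and edgeR 1. For the KRT5 classes edgeR recovered 100% at every fold, and for the ESR1 classes 96% at 2-fold and 100% above. For the interaction it recovered 54% at 2-fold and 100% above. Unchanged genes made up 14 of 214 edgeR calls for KRT5, 11 of 209 for ESR1 and 13 of 190 for the interaction. For DESeq2 they were 5 of 205, 3 of 198 and 2 of 173. The simulated spread followed the fitted trend with expression level, without the added spread of single genes. Recovery of real genes that varied more between libraries could thus be lower than these shares. KRT6A, for example, had a log2 of 1.65 (SE 0.46, edgeR adjusted p = 0.77) between the real KRT5 classes and was not called. Chromosome copy number and sequence variants were not analysed here.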

Results

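RNA from single cells of 4 human breast cancer xenografts was counted, with 2 xenografts grown under estradiol and 2 under placebo. The kept cells numbered 1441 and 1665 in estradiol replicates 1 and 2, and 1549 and 776 in placebo replicates 1 and 2. Median depth was 21944 and 54434 UMIs per cell in the estradiol libraries and 21446 and 27564 in the placebo libraries. Each library was 1 xenograft line with no repeat, so library values below have no replicate error.

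The xenografts were strongly different tumours, each with its own set of abundant genes. Estradiol replicate 1 had a secretory luminal profile. TFF3, a secreted mucosal peptide and known estrogen target, stood at 568 CPM, 327 times the next library (95% interval 265 to 409). SPDEF, a transcription factor of luminal secretory cells, stood at 199 CPM, 235 times the next library (155 to 375). DEFB1, MUCL1, CFD and PSCA completed its set, at 70.9, 70.7, 34.1 and 28.7 times the next library. Placebo replicate 1 had a matrix profile. COL6A3, a chain of type VI collagen, stood at 240 CPM, 2085 times the next library (713 to 10111), on 3 UMIs in that library. MMP2, a gelatinase, stood at 401 CPM, 528 times the next (418 to 676). MXRA8, PLAC9, FMOD and SCIN were 1000, 365, 121 and 111 times the next library. Placebo replicate 2 was set apart by MAGEA4, a cancer-testis antigen, at 553 CPM and 270.5 times the next library (235 to 314). EREG, an EGFR ligand, stood there at 915 CPM and 196 times the next (169 to 229). S100A7, RAMP1, AKR1C2 and PAPPA were 122, 59.7, 41.9 and 29.9 times the next library. Estradiol replicate 2 was set apart by CRABP1, a retinoic acid binding protein, at 455 CPM and 73.9 times the next library (66 to 83). RASD2, DIO2, MARCO, LTF and TNFSF13B followed at 69.2, 48.7, 43, 36 and 33 times. Among the fixed lists, 7 of the 14 EMT genes in all tables were at least 4 times higher in placebo replicate 1 than in any other library. For the luminal identity list the same held for 3 of 16 genes in estradiol replicate 1. These folds compare single libraries and have no test.

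**Figure D1:**
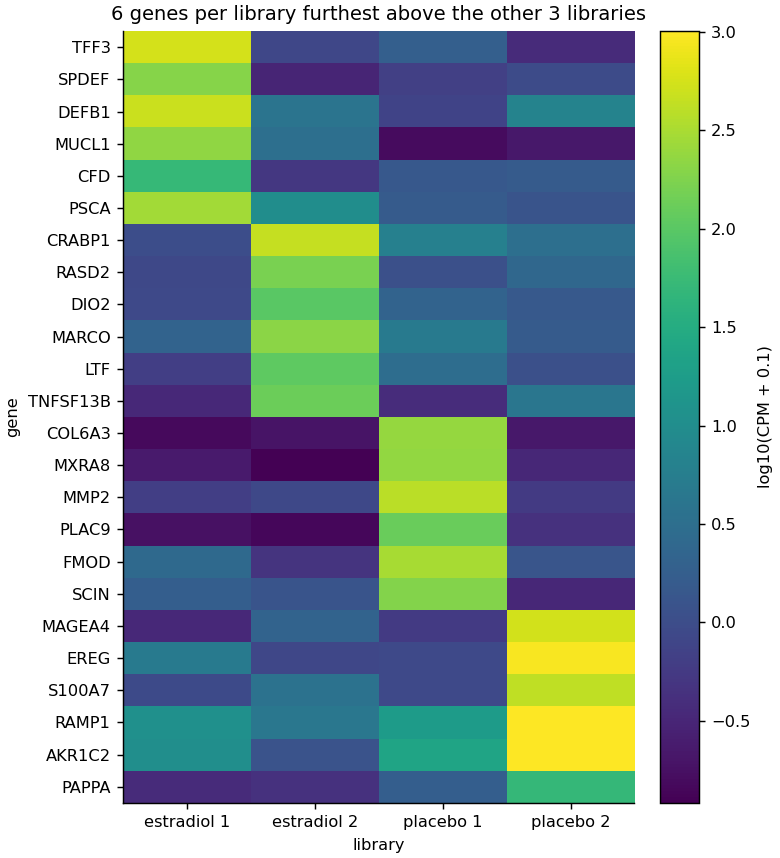
Level of the 6 genes per library that stood furthest above the other libraries, as log10(CPM + 0.1) by colour, with genes as rows and the 4 libraries as columns. Each block of 6 is bright in 1 library, as TFF3 at 568 CPM in estradiol replicate 1 and COL6A3 at 240 CPM in placebo replicate 1.

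Cells within each xenograft fell into several states, and a cycling state was present in every library. Clustering gave 6 and 8 clusters in estradiol replicates 1 and 2 and 8 and 4 in placebo replicates 1 and 2. Cycling-like clusters held 8.54% and 24.7% of cells in the estradiol libraries and 4.33% and 13.9% in the placebo libraries. These clusters did not hold every cycling cell. Only 637 of 1441 and 970 of 1665 estradiol cells and 1193 of 1549 and 405 of 776 placebo cells had no UMI of MKI67, TOP2A or CDK1, counts that also depend on depth. In estradiol replicate 1 an unnamed cluster of 22.1% of cells was led by replication genes such as RRM2 and PCNA, with MKI67 in 52.2%. A basal-like cluster held 16% of estradiol replicate 1, with a UMI of KRT5, itself 1 of the naming markers, in 33.3% of its cells. A cluster named basal-like by the marker rule also held 31.2% of placebo replicate 2, but KRT5 did not set it apart, with a UMI in 50.4% of its cells against 49% to 79.6% in the other clusters. In placebo replicate 1, an unnamed cluster of 30 cells had KRT5 in 100% of cells at 2422 CPM and KRT18 in 100%, with 4 luminal and 4 basal markers raised. COL2A1, the main collagen of cartilage, was found in 98.7% of cells of the largest cluster of that library, at 6422 CPM, against 39.9% and 179 CPM in a cluster of PTPRC-bearing cells. A fibroblast-like cluster there held 16.3% of cells, with COL1A1 in 97.2% and B2M in 96.8%. These are counts of cells in single libraries, and doublets were not removed. The number of clusters moved with the resolution.

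Both a placebo and an estradiol library held a second population with few long non-coding RNA UMIs. It made up 27.5% of placebo replicate 1 (25.3 to 29.8) and 19.3% of estradiol replicate 2 (17.4 to 21.3), against 0 of 1441 cells in estradiol replicate 1 and 4 cells in placebo replicate 2. Its median depth was 3504.5 UMIs in placebo replicate 1 and 3133 in estradiol replicate 2, against 33563 and 67342.5 in the other cells. The deposited tables of estradiol replicate 1 and placebo replicate 2 held no cell below 7332 and 5376 UMIs. In placebo replicate 1 and estradiol replicate 2 the lowest totals were 503 and 567. Cells at those median depths could not appear in estradiol replicate 1 or placebo replicate 2, so the shares are not comparable between libraries. Deeper ones could appear. A cluster of 42 such cells in estradiol replicate 2 had a median of 8642 UMIs, and the 4 in placebo replicate 2 had a median of 10151.5. The near-absence in those 2 libraries thus covers only cells above their lowest totals. B2M, the light chain of MHC class I, was found at 1900 UMIs per cell in 2.06% and 14.6% of these cells, against 47.2% and 82.9% of the other cells. COL1A1, a fibrillar collagen, reached 27112 CPM in 1 such cluster of placebo replicate 1. Another cluster there had PTPRC, a leukocyte marker, in 32.2% of cells. The threshold of 0.2% was chosen after the data were seen, with 56 cells of placebo replicate 1 and 71 of estradiol replicate 2 between 0.15% and 0.25%.

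**Figure D2:**
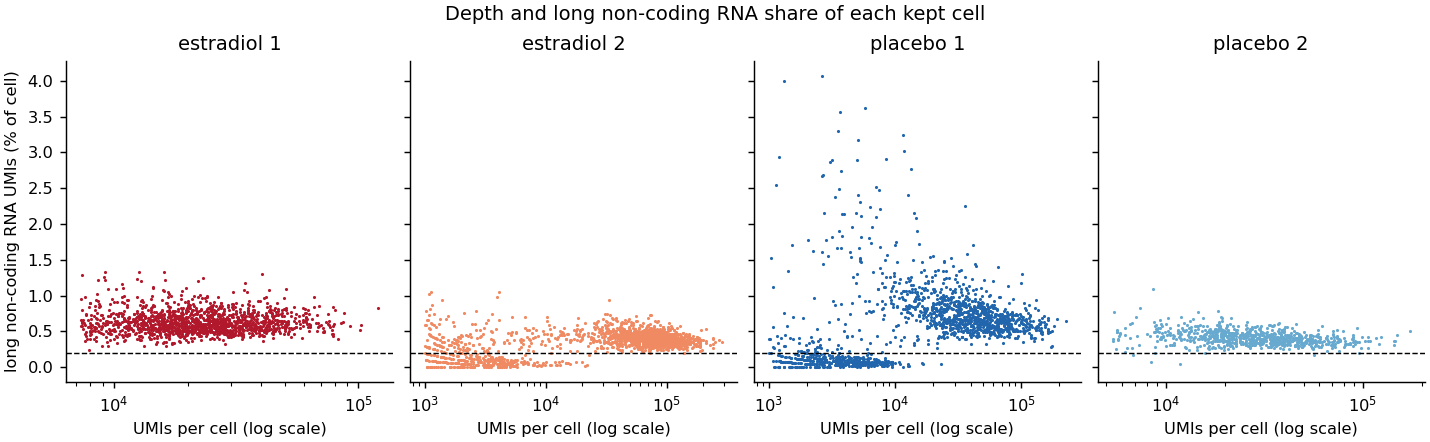
Each point is a kept cell, with its UMIs on a log axis against the percent of them from long non-coding RNA genes, 1 panel per library. Below the dashed line at 0.2% lie 27.5% of cells in placebo replicate 1 and 19.3% in estradiol replicate 2, and 0 and 4 cells in the other libraries. The tables of those other libraries held no cell below 7332 and 5376 UMIs.

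Which cells carried basal keratins, epithelial markers and hormone receptors was read from shares of cells with a UMI. At 1900 UMIs per cell, KRT5, a basal keratin on chromosome 12 (52514575 to 52520687), was found in 1.6% (1.01 to 2.39) and 7.77% (6.47 to 9.24) of estradiol cells. In the placebo libraries the shares were 9.3% (7.85 to 10.9) and 9.66% (7.68 to 12). Unthinned, the same shares were 11.4% and 28.5% against 22.1% and 57.2%. KRT14, another basal keratin, was found in 0.139% and 1.4% of estradiol cells and in 34.5% and 9.28% of placebo cells at 1900 UMIs. EPCAM, an epithelial adhesion molecule, was found in 45% and 39.9% against 0.839% and 25.4%. ESR1, the estrogen receptor gene on chromosome 6 (151656691 to 152129619), was found in 0.208% and 0.332% against 0.839% and 0.644%. These 4 genes did not overlap between treatments at that depth, and unthinned only EPCAM and KRT14 did not overlap. By CPM, 34.6% of all tested genes did not overlap, where chance gives 33.3%, so some markers would stand apart without any effect of treatment. For KRT5 the intervals of estradiol replicate 2 and placebo replicate 1 overlapped. ESR1 overlapped among human-profile cells, at 0.208% and 0.237% under estradiol against 0.0917% and 0.777% under placebo, since most ESR1-positive cells of placebo replicate 1 had few long non-coding RNA UMIs. The ESR1 shares at this depth rest on few cells, and the random thinning alone moves them. In placebo replicate 2 the share rose from 0.644% to 0.777% although only 4 cells were left out. VIM ranged from 7.22% in estradiol replicate 1 to 97.1% in placebo replicate 1. KRT17 ranged from 17.8% in placebo replicate 1 to 98.6% in placebo replicate 2. KRT18, MKI67, TOP2A and ERBB2 overlapped between treatments, with KRT18 between 4.76% and 68.5%. PGR, absent from the table of placebo replicate 2, was found in at most 0.14% of cells, with 0 of 1505 in estradiol replicate 2, which allows up to 0.245%. Cells below 1900 UMIs were left out, 119 in placebo replicate 1 and 160 in estradiol replicate 2. In the PTPRC-bearing cluster of placebo replicate 1, which should lack keratins, 3.85% of cells had a KRT5 UMI at a median of 2391.5 UMIs. The share over that library was 9.3% at 1900 UMIs and 22.1% at a median of 21446. KRT5 stood at 21.3 CPM in this cluster, against 17.4 and 17.1 CPM in clusters holding 17.6% and 11.3% of the library. By CPM those clusters thus cannot be told from the PTPRC-bearing one. By cell they differed, with a KRT5 UMI in 13.6% and 10.3% of cells at medians of 28749 and 22915 UMIs. Whether the KRT5 UMIs of those clusters are background is therefore left open. The matching cluster of estradiol replicate 2 had KRT5 in 1.33% of cells at 2030.5 UMIs. The share over that library was 7.77% at 1900 UMIs and 28.5% at a median of 54434. KRT14 was found at 1900 UMIs in 13.5% of the cells of placebo replicate 1 with few long non-coding RNA UMIs, from a source that was not tested. ESR1 was found in 0.962% of the PTPRC-bearing cluster of placebo replicate 1 and in 0 of 150 cells of the matching cluster, unthinned.

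**Figure D3:**
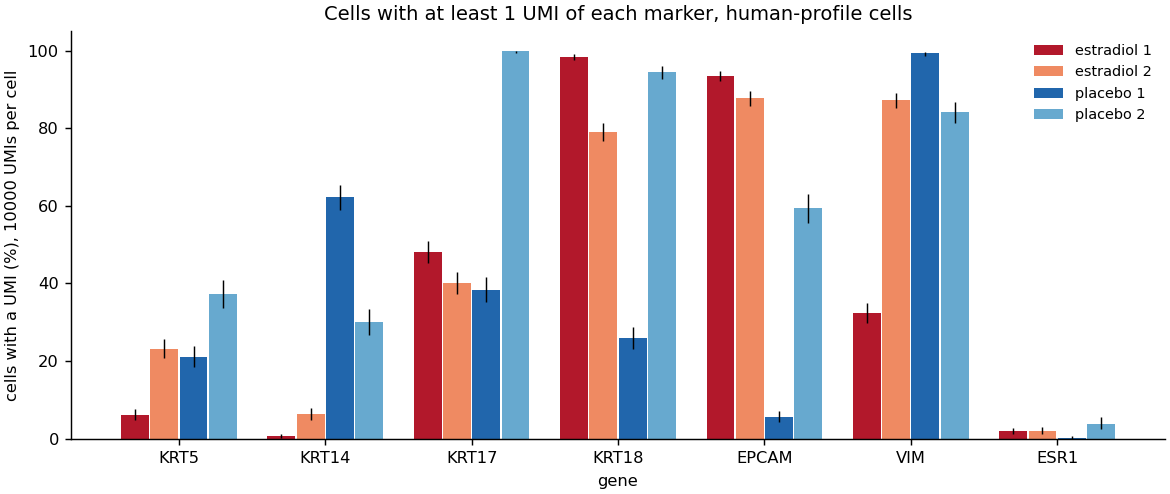
Percent of human-profile cells with at least 1 UMI of each gene after thinning to 10000 UMIs per cell, with exact 95% intervals, 1 bar per library. KRT5 stood at 6.18% and 23.1% in the estradiol libraries and 21.1% and 37.3% in the placebo libraries.

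The comparison of treatments asked which genes and gene groups differed between estradiol and placebo xenografts. Most luminal and lipid-synthesis genes had positive changes and most mesenchymal, hypoxia and cornified-layer genes negative ones, but the libraries of the groups overlapped for many of them. Without overlap between groups, 6 of 16 luminal, 7 of 13 fatty acid and 10 of 22 cholesterol genes were higher under estradiol, and 10 of 24 hypoxia and 2 of 13 cornified-layer genes were lower. Of 14 EMT genes 1 was higher and 1 lower. Of 31 interferon genes 10 were higher and 0 lower, and of 51 G2/M genes 14 were higher and 5 lower. Over all 14400 genes 2410 were higher and 2566 lower without overlap. Both directions together made up 34.6%, where chance gives 33.3%, so counts in 1 direction are to be set against the 2410 or the 2566. Members of a list can vary together, so these counts are no test. Of the luminal identity list, 15 of 16 members had positive changes with a median log2 of 1.64, and camera called the list higher (adjusted p = 3.7e-05, but adjusted p = 0.652 with an estimated correlation). Summed, the list overlapped, at 11528 and 4234 CPM under estradiol against 1303 and 4590 under placebo. GATA3, a luminal transcription factor, had a log2 fold change of 2.40 (SE 0.89), with CPM of 38.1 and 46.8 against 4.08 and 12. KRT7 stood at 2.69 (SE 0.84) and SPDEF at 7.19 (SE 2.51), the latter from estradiol replicate 1 alone. No gene passed the threshold. edgeR called 0 of 14400 genes with 872 at unadjusted p under 0.05, limma on mean CPM called 0 with 647, and DESeq2 called 304 with 128 higher and 176 lower.

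Lipid genes followed the luminal list. For fatty acid synthesis 12 of 13 members were positive with a median of 1.33, and for cholesterol synthesis 20 of 22 with a median of 0.91. Camera called both higher, at adjusted p = 1.2e-04 and 3.1e-04 (adjusted p = 0.652 for each with an estimated correlation). FADS2 and FADS1, fatty acid desaturases, stood at 4.87 (SE 1.31) and 2.002 (SE 0.82), and ACSS2 at 2.72 (SE 1.04). In the cholesterol pathway MSMO1 stood at 2.11, MVD at 2.46 and MVK at 1.69. Interferon genes were positive in 24 of 31 cases with a median of 1.44 (camera adjusted p = 1.2e-04, adjusted p = 0.652 with an estimated correlation). Summed, they stood at 1842 and 2252 CPM against 229 and 1378, with placebo replicate 1 furthest from the others. IFI27, an interferon-induced gene, was found at 559 and 405 CPM under estradiol against 8.09 and 13.3 under placebo, a log2 of 5.49 (SE 0.95, adjusted p = 0.811). RSAD2 and IFIT3 stood at 2.55 and 2.84. Mitochondrially encoded genes were positive in 12 of 13 cases with a median of 0.56 (adjusted p = 0.0311, 0.652 with an estimated correlation), led by MT-CO2 at 1.79, MT-ND4 at 1.52 and MT-ND2 at 1.41. The median mitochondrial share of kept cells was 7.37% and 9% in the estradiol libraries and 3.43% and 2.8% in the placebo libraries. The deposited tables differed in range, with highest shares of 69.7% and 29.9% under estradiol and 19.98% and 9.83% under placebo. Placebo replicate 2 thus held no cell above 9.83%, while cells up to 20% were kept elsewhere. The medians and the mitochondrial list call cannot be separated from this difference. G2/M genes were positive in 38 of 51 cases with a median of 0.45 (adjusted p = 0.0311, 0.795 with an estimated correlation). RANGAP1 and GAS2L3 stood at 1.80 and 1.67, and CBX5 at -1.57.

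Lower lists were led by EMT. Only 3 of 14 EMT members were positive and the median was -3.11 (camera adjusted p = 0.0124, adjusted p = 0.652 with an estimated correlation). Summed, these genes were highest in placebo replicate 1, at 13780 CPM, and lowest in placebo replicate 2, at 3690 CPM. S100A4, a calcium-binding protein of motile cells, stood at 100 and 143 CPM against 1742 and 657, a log2 of -3.30 (SE 0.86). MMP2 stood at -8.15 and FN1, fibronectin, at -4.98, both carried by placebo replicate 1 at 384 and 1939 CPM (scaled by TMM factors in this comparison). Hypoxia genes were positive in 4 of 24 cases with a median of -0.54 (adjusted p = 0.0147, 0.652 with an estimated correlation). CA9, a hypoxia-induced carbonic anhydrase, stood at -3.01 (SE 1.07), P4HA1 at -2.39 and ENO2 at -1.81. Cornified-layer genes were positive in 2 of 13 cases with a median of -1.39 (adjusted p = 0.0341, 0.652 with an estimated correlation), with KLK7 at -3.00, IVL at -2.54 and S100A7 at -6.67, the last carried by placebo replicate 2. The 12 other lists were not called. Estrogen-induced genes were split, with 16 of 32 positive and a median of 0.00 (camera adjusted p = 0.575). Basal genes were positive in 13 of 24 cases with a median of 0.12, while their mean was -0.37 and the test pointed down (adjusted p = 0.264). Within that list KRT14 stood at -6.77 (SE 1.98), KRT17 at -3.59 (SE 1.20) and KRT5 at -1.32 (SE 1.002). KRT8 stood at 1.48 and KRT18 at 0.80, GREB1 at 0.85, ESR1 at -0.29 and MKI67 at -0.29. Adjusted over the list alone, 1 gene was called higher in each of the interferon, luminal progenitor and NF-kB lists and 1 lower in the steroid receptor list, against 0 over all genes tested. All 9 list calls were lost with an estimated correlation and with fry. Without estradiol replicate 1 the preset test called 4 lists, without placebo replicate 1 it called 5, and without cycling cells 5.

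**Figure D4:**
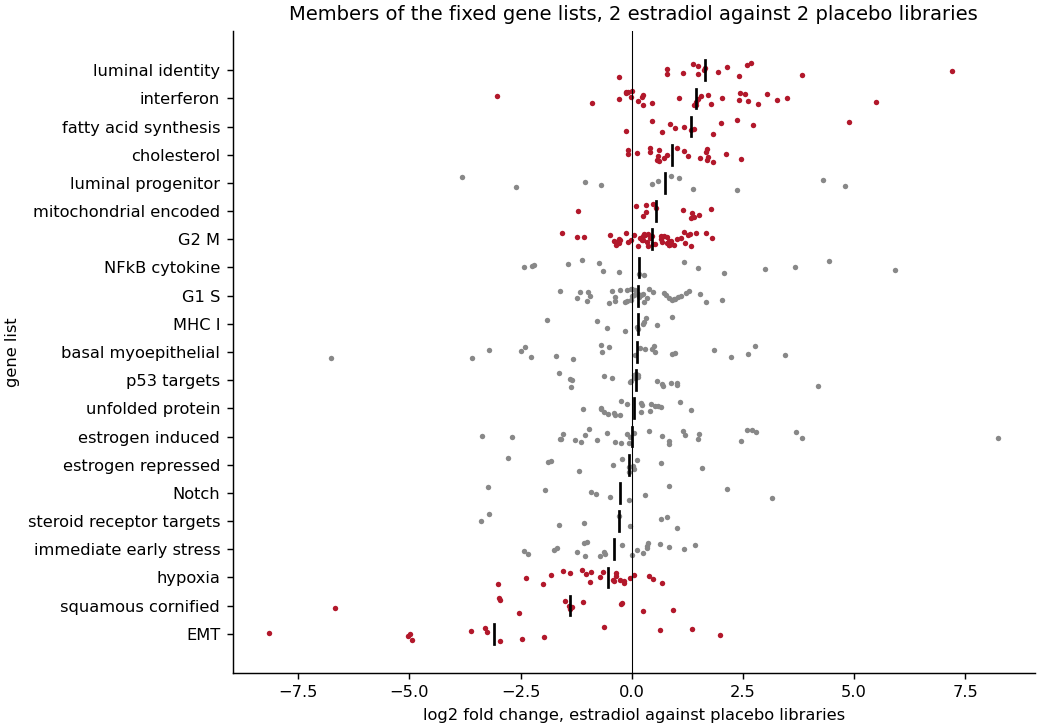
Each point is the log2 fold change of 1 list member between 2 estradiol and 2 placebo libraries, with black bars at list medians and red for lists called by camera with the preset correlation. Luminal identity has the highest median at 1.64 and EMT the lowest at -3.11.

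KRT5-positive cells were compared with KRT5-negative cells of the same library, matched for depth, to describe what else cells with a KRT5 UMI expressed. In placebo replicate 2 the depths stayed apart, with medians of 28528.5 and 21215 UMIs in positive and negative cells. Of the KRT5-positive cells of placebo replicate 1, 7.29% had few long non-coding RNA UMIs. The classes were also spread unevenly over clusters, which the matching did not address. Of 343 KRT5-positive cells in placebo replicate 1, 111 lay in the COL2A1-rich cluster, 88 in the fibroblast-like one and 30 in the keratin-rich one, which held 45.7% of the KRT5 UMIs. In estradiol replicate 1 a cluster was led by secretory genes such as PIP together with the hypoxia genes EGLN3 and NDRG1. It had KRT5 in 4.08% of cells, against 33.3% in the basal-like one, at medians of 16612 and 25087 UMIs. By level KRT5 stood at 5.65 CPM there, at 5.93, 5.01, 5.30 and 17.5 CPM in the remaining clusters, and at 51 CPM in the basal-like one. The cluster with hypoxia genes was thus not particularly low in KRT5. Hypoxia genes were lower in KRT5-positive cells. All 24 hypoxia genes had negative changes over the 4 libraries, with a median log2 of -0.45, and 16 of 24 were lower in each library. The library medians were -0.30 and -0.39 in estradiol replicates 1 and 2 and -0.72 and -0.25 in placebo replicates 1 and 2. ANKRD37, a HIF target, stood at -0.62 (SE 0.08, adjusted p = 0.213), P4HA1 at -0.60 (SE 0.11) and NDRG1 at -0.57 (SE 0.10), and all 3 were lower in every library. Adjusted over the list alone, 15 of 24 hypoxia genes were called lower, against 0 over all genes tested. Camera called the list lower (adjusted p = 7.2e-28, but adjusted p = 0.745 with an estimated correlation). When the classes were swapped in some libraries, a check chosen after seeing the data, 7 of the 8 splits called at least as many lists as the real one. Several swapped splits also had all 24 hypoxia genes going 1 way.

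Several other basal keratins went with KRT5. KRT6A, a stress-associated basal keratin, had a log2 of 1.65 (SE 0.46, adjusted p = 0.77), with 275 against 49.2 CPM in estradiol replicate 1 and higher values in every library. KRT14 stood at 0.99 (SE 0.45), KRT16 at 0.59 (SE 0.23) and CDH3, P-cadherin, at 0.43 (SE 0.16), each higher in every library, and KRT17 at 1.04 (SE 0.55), higher in 3. Basal genes were positive in 20 of 23 cases with a median of 0.27 (camera adjusted p = 1.1e-06, adjusted p = 0.789 with an estimated correlation). Library medians were 0.75 and -0.08 under estradiol and 0.46 and 0.25 under placebo, with 15 of 23 genes lower in estradiol replicate 2. Luminal genes were positive in 11 of 16 cases with a median of 0.37 (adjusted p = 0.017, 0.802 with an estimated correlation), with library medians of -0.09 and 0.12 under estradiol and 0.97 and 0.10 under placebo. KRT19, KRT8 and KRT18 stood at 0.67, 0.46 and 0.37, and MUC1 and AGR2 at -0.23 and -0.54. G1/S genes were positive in 39 of 41 cases with a median of 0.18 (adjusted p = 6.3e-09), and G2/M genes in 49 of 51 with a median of 0.15 (adjusted p = 1.1e-06), each with adjusted p = 0.789 with an estimated correlation. EXO1 stood at 0.75, UNG at 0.30 and TYMS at 0.30 in G1/S, and KIF20B at 0.25, TPX2 at 0.19, SMC4 at 0.17 and MKI67 at 0.29 in G2/M. Library medians for G1/S were 0.07 and 0.01 under estradiol and 0.44 and 0.14 under placebo, and for G2/M -0.04 and 0.11 against 0.38 and 0.06, so placebo replicate 1 was highest in both and estradiol replicate 1 went the other way in G2/M. Notch genes were positive in 7 of 8 cases with a median of 0.22 (adjusted p = 0.0266, 0.789 with an estimated correlation), with NRARP at 0.71, NOTCH3 at 0.46 and NOTCH1 at 0.31. Unfolded-protein genes were negative in 17 of 20 cases with a median of -0.14 (adjusted p = 2.3e-04, 0.789 with an estimated correlation), with SEL1L at -0.26, PDIA4 at -0.20 and PDIA6 at -0.19. ESR1 stood at 0.61 (SE 0.31) and GREB1 at -0.01 (SE 0.25). Adjusted over the list alone, 2 estrogen-induced genes were called lower and 1 NF-kB gene higher, against 0 over all genes tested. edgeR called 0 of 13128 genes with 805 at unadjusted p under 0.05, and DESeq2 called 15, with 4 higher and 11 lower. KRT6A, ANKRD37, NDRG1 and P4HA1 were among the DESeq2 calls, and KRT6A was the gene called by edgeR without estradiol replicate 2 (log2 of 2.18).

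**Figure D5:**
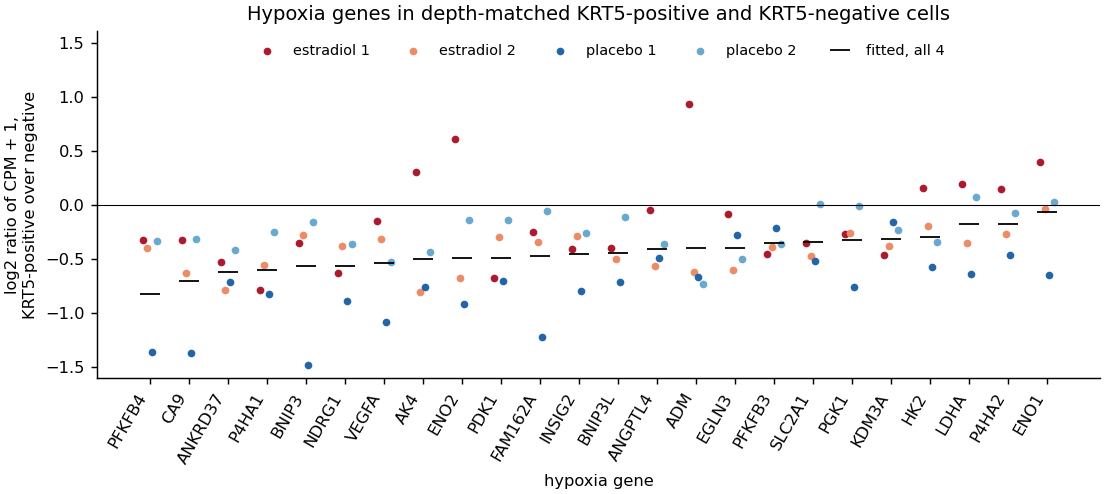
Log2 ratio of CPM + 1 in KRT5-positive over depth-matched KRT5-negative cells for 24 hypoxia genes, with 1 coloured point per library and a black bar for the value fitted over the 4. Every bar lies below 0, and 16 genes lie below 0 in each library.

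Whether the KRT5 contrast differed with treatment was tested as an interaction, and 2 of 13128 genes were called, with 461 at unadjusted p under 0.05. S100A8, a calprotectin subunit of inflamed epithelium, was 2.17 log2 units (SE 0.19, adjusted p = 0.018) higher in the contrast of estradiol than of placebo libraries. In placebo replicate 2 it stood at 327 CPM in KRT5-positive and 1575 in KRT5-negative cells, against 378 and 370 in estradiol replicate 1. C2orf40, which encodes the secreted peptide augurin, was 2.79 units lower (SE 0.24, adjusted p = 0.029). In estradiol replicate 2 it stood at 3.1 and 22.8 CPM, against 2794 and 3269 in placebo replicate 1, and it had 0 UMIs in both classes of estradiol replicate 1. Both genes were named because they were the only calls, after their values were seen. The number called was 0 without matching, 0 at 2 UMIs, and 122 without placebo replicate 2. Without estradiol replicate 2 the value of C2orf40 was 0.11, so that call rests on 1 estradiol library. S100A8 stayed between 1.70 and 2.36 over 10 alternatives, but its call was lost in 6 of them. In 20 random splits of KRT5-negative cells, a check chosen after seeing the data, the class contrast called 0 to 7 genes. A count of 2 lies within that range, but the interaction was not run on such splits.

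ESR1-positive cells were compared with ESR1-negative cells of the same library and depth, in 325 pairs. The G2/M list was called higher in the ESR1-positive cells, and the run without cycling cells does not test this, since it removes the cells that carry these genes. G2/M genes were positive in 50 of 51 cases with a median log2 of 0.34 (camera adjusted p = 6.9e-11, adjusted p = 0.937 with an estimated correlation). AURKA, a mitotic kinase, stood at 0.72 (SE 0.22), DLGAP5 at 0.67 (SE 0.19) and KIF23 at 0.50 (SE 0.16). The list was higher in placebo replicate 2 and estradiol replicate 2, with medians of 0.78 and 0.37, but not in estradiol replicate 1, at -0.18. In placebo replicate 1 the median was 0.00, with 23 genes lower, 17 higher and the rest equal. DLGAP5, for example, stood at 0 CPM in both classes there, so the 0.00 is no measured absence of a difference. G1/S genes were called lower, with 14 of 39 positive and a median of -0.06 (adjusted p = 1.0e-05, 0.937 with an estimated correlation), and were not called among human-profile cells (adjusted p = 0.0876). Their library medians were -0.10 and 0.03 under estradiol and -1.68 and -0.10 under placebo, with PCNA at -0.40, MCM5 at -0.39 and E2F8 at 0.49. The -1.68 came from 42 ESR1-positive cells of placebo replicate 1 at a median of 6108.5 UMIs, with MCM5 at 0 against 17.7 CPM. The luminal list had the same median there, since ratios of CPM + 1 take few values at such low counts. Its size thus cannot be read as a fold change. Keratins KRT5, KRT8, KRT18, KRT17 and KRT14 stood at 0.29, -0.05, -0.19, -0.38 and -0.63, with SEs from 0.24 to 1.07, and MKI67 at 0.34. Estrogen-induced genes were positive in 14 of 24 cases with a median of 0.05 (adjusted p = 0.837). Adjusted over the list alone, 1 basal gene was called higher, against 0 over all genes tested. edgeR called 0 of 10537 genes with 248 at unadjusted p under 0.05, and DESeq2 called 0 with 104. In placebo replicate 1, 36 of 42 ESR1-positive cells had few long non-coding RNA UMIs. Among human-profile cells, where that library had too few ESR1-positive cells to enter, edgeR called 3 genes, SYT8 at 0.98 (SE 0.14), LOXL4 at 1.27 (SE 0.19) and C2orf82 at -1.37 (SE 0.21), while a split with the classes of 1 library swapped called 14.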

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

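All tests in this part were chosen after the results were seen, except the planned interaction of KRT5 class with treatment. That test of the difference itself called S100A8, at 2.17 log2 units, and C2orf40, at -2.79. C2orf40 had 0 UMIs in both classes of estradiol replicate 1 and a value of 0.11 without estradiol replicate 2, so its estradiol side was 1 library. PCNA, a replication clamp, was higher in the ESR1-positive cells of both estradiol libraries and lower in those of both placebo libraries. The gap between the mean values was 1.36 log2 units, and this difference was not tested. It came mostly from placebo replicate 1, at 25.6 against 99.5 CPM, where 36 of 42 ESR1-positive cells had few long non-coding RNA UMIs, while estradiol replicate 1 stood at 42 against 41.6 CPM.

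A few values lay far from those of the other 3 libraries. In the ESR1 contrast, placebo replicate 1 stood apart for KRT18 at -3.41 log2 (others -0.11 to 0.09), KRT8 at -1.53 (0.07 to 0.39), MCM5 at -4.22 (-0.61 to -0.10) and the G1/S list at -1.68 (-0.10 to 0.03). These are ratios of CPM + 1 from 42 shallow ESR1-positive cells. KRT18 stood there at 2.84 against 39.8 CPM and MCM5 at 0 against 17.7 CPM. The KRT18, MCM5 and G1/S values thus lie at or near the counting floor, and their size cannot be read. In the KRT5 contrast placebo replicate 1 stood apart for KRT8 at 1.31 (0.08 to 0.28), KIF20B at 0.35 (0.18 to 0.20) and the Notch list at 0.52 (0.06 to 0.10). Estradiol replicate 1 stood apart in the KRT5 contrast for SEL1L at -0.59 (-0.17 to -0.16) and the unfolded-protein list at -0.39 (-0.10 to -0.09). Of 49 sets of 4 values examined, 9 had such a value, and chance gives about 1 in 20. The sets were not independent, since MCM5 belongs to the G1/S list and SEL1L to the unfolded-protein list. The 9 thus cannot be read as an excess over chance. The values at the counting floor are among the 9.

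Genes that were not listed in all 4 tables, and so were outside the comparisons, held strong signals in single libraries. Estradiol replicate 1 had SCGB2A2, which encodes mammaglobin, at 13399 CPM and LRRC26 at 175 CPM. Placebo replicate 1 had MEG3, an imprinted long non-coding RNA, at 952 CPM. Placebo replicate 2 had CLDN10 at 550 CPM and TESC at 340 CPM, and estradiol replicate 2 had the chemokine CCL3 at 513 CPM.

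The cells with few long non-coding RNA UMIs in placebo replicate 1 and estradiol replicate 2 were weighed first. Shallow human cells would carry B2M as often as others at equal depth, but 14.6% did in estradiol replicate 2, against 82.9%, and the gap was wider in placebo replicate 1. Human stromal cells would keep B2M, but the highest level in a cluster of these cells was 137 CPM, below the lowest of the other clusters, 264 CPM. Mouse cells left after depletion and read against the human genome may account for them, since their highest median mitochondrial share was 0.997%, against at least 5.49% in the other cells. By cluster the gap was narrower, with 1.57% in a cluster made mostly of these cells and 2.24% in another cluster of placebo replicate 1. No mouse genome was used, so this stays a hypothesis.

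The ESR1 UMIs of placebo replicate 1 followed the same cells. Of its ESR1-positive cells 85.7% (71.5 to 94.6) had few long non-coding RNA UMIs, against 27.5% of all its cells, which may place these UMIs in mouse cells. Background RNA would give all such cells a like share, but it was 0.962% in the PTPRC-bearing cluster and 15.6% in the COL1A1-rich one. The depth of these clusters differed, at 2391.5 and 4969 UMIs. No biological explanation was tested.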

How the results depend on the processing

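The alternatives with human-profile cells, genes in any table, pairs within 10% of depth, no top 5% of cells, cycling cells left out of the KRT5 and ESR1 fits, and every list alternative beyond the estimated correlation and fry were chosen after seeing the data. The treatment comparison called 0 genes with edgeR under every alternative, and 304 with DESeq2. In the counts simulated for this comparison DESeq2 called 84 unchanged genes and edgeR 1. No paired analysis of treatment was possible because no line was measured under both. The KRT5 contrast called 15 genes with DESeq2 and 2 with at least 2000 UMIs and at most 10% mitochondrial UMIs, and 0 to 1 with 1 library left out. The ESR1 contrast called 1 gene with no filter on low counts, 3 in human-profile cells, 1 without cycling cells, and 0 to 5 with 1 library left out (5 without placebo replicate 1). In human-profile cells leaving out 1 more library gave 3 to 64. The 2-UMI class for ESR1 was not run, since only 1 library had 20 such cells. The interaction called 1 gene in human-profile cells, 0 without matching, 1 with pairs within 10% of depth, 0 at 2 UMIs, and 0 to 122 with 1 library left out (122 without placebo replicate 2). Without cycling cells its 2 calls were other genes. Where 1 library of a treatment was left out, the lone library was assumed to vary like the others. The cause of these moves was not tested.

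An estimated correlation and fry each called 0 lists in the 3 contrasts of kept cells. Among human-profile cells fry called the unfolded-protein list lower in ESR1-positive cells (adjusted p = 0.036). For treatment, 5 lists were called without cycling cells and 4 to 9 with 1 library left out. The 9 without estradiol replicate 2 were 3 higher and 6 lower, against 6 higher and 3 lower in the main run. For KRT5, 4 to 11 were called with 1 library left out (4 without placebo replicate 1, 11 without placebo replicate 2). For ESR1, 8 were called in human-profile cells, 4 without matching, and 3 to 7 with 1 library left out. The hypoxia list stayed lower in KRT5-positive cells under each of these list settings, with medians from -0.68 at 2 UMIs to -0.35 without cycling cells, and 23 or 24 of 24 genes negative.

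At 20 CPM the smallest fold of the 6 library genes was 57.7 in estradiol replicate 1 and 59.7 in placebo replicate 2. In human-profile cells it was 145 in placebo replicate 1 and 40.7 in placebo replicate 2. With genes in any table, where a gene absent from a table was entered as 0, it was 176 and 73.9 in estradiol replicates 1 and 2, and 2771 and 101 in placebo replicates 1 and 2. Unthinned, 2 marker shares did not overlap between treatments, against 4. Clusters numbered 3 in estradiol replicate 1 at resolution 0.3. At resolution 1.0 they numbered 10 there, 14 in placebo replicate 1 and 9 in placebo replicate 2.

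Of 559 refits of 35 named genes for treatment, 542 kept direction and call, 8 gained a call and 9 changed sign. With 1 library left out, ESR1 ranged from -0.95 to 1.08, GREB1 from -0.030 to 1.41, KRT18 from -0.44 to 3.23 and MKI67 from -1.58 to 0.89. MMP2 ranged from -9.14 to 0.50 (0.50 without placebo replicate 1), S100A7 from -7.97 to 1.58 (1.58 without placebo replicate 2) and SPDEF from -1.69 to 8.21 (-1.69 without estradiol replicate 1). Of 502 refits of 28 genes in the KRT5 contrast, 12 changed sign. GREB1, near 0, was 0.021 with DESeq2, 0.092 without the top 5%, 0.82 without cycling cells, 0.015 without matching, 0.21 at 2 UMIs, 0.086 without the block, and -0.18 to 0.10 with 1 library left out. ESR1 was -0.19 without matching, and without cycling cells SMC4, TPX2 and TYMS were -0.16, -0.076 and -0.21. Of 198 refits of 12 genes in the ESR1 contrast, 17 changed sign. KRT14 was 0.35 with DESeq2, 0.41 in human-profile cells and -1.34 to 0.53 with 1 library left out. KRT17 was 0.31 without the top 5%, 0.33 in human-profile cells and -1.15 to 0.40 with 1 library left out. KRT8 was 0.0056 under the stricter cell filter, 0.074 without the top 5%, 0.18 in human-profile cells, 0.069 without cycling cells, 0.19 without the block and -0.26 to 0.19 with 1 library left out. KRT18 was 0.011 without the top 5% and 0.015 without cycling cells, KRT5 was -0.17 without cycling cells and -0.20 without matching, and MCM5 was 0.18 without cycling cells. Of 20 refits of the 2 interaction genes, 7 kept direction and call, 12 lost the call and 1 changed sign. C2orf40 ranged from -2.94 to 0.11 with 1 library left out, and S100A8 from 1.70 to 2.36 over all alternatives. The ESR1 contrast had 42 to 126 positive cells per library.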

Other observations

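The tests of explanations and the splits in this part were chosen after the results were seen, while the clusters and their settings were planned. Estradiol replicate 1 held a cluster of 16% of its cells led by KRT6A, ISG15, OASL, KRT17 and RSAD2, basal keratins and interferon genes. A further 23.8% of its cells were led by PIP, SCGB1D2, BPIFA2 and TFF1, genes of secretory and apocrine epithelium, together with EGLN3 and NDRG1 of the hypoxia list. Placebo replicate 1 had a cluster led by MATN4, EPYC, FRZB and COL2A1, genes of cartilage, in 20.3% of cells, and 1 led by LUM, ASPN and PDGFRB in 16.3%. Placebo replicate 2 had a cluster led by APOBEC3A, IFI6 and MX1 in 31.2% of cells. Estradiol replicate 2 had a cluster led by CCL3 in 23.2% of cells and 1 led by MMP7, LCN2 and LTF, genes of mucosal defence, in 9.73%. These genes led because they define the clusters.

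The lower hypoxia genes of KRT5-positive cells were weighed against technical explanations. With pairs within 10% of depth the median of the 24 genes was -0.44, against -0.45 over all pairs, which argues against a depth gap within the pairs. Without cycling cells it was -0.35, and among human-profile cells -0.44, with all 24 genes negative in each. The move from -0.45 to -0.35 means that cycling cells may account for part of the difference. Cells with few long non-coding RNA UMIs among the negative ones would have brought the human-profile value near 0 if they were the source. Where the hypoxic cells lay in the tumours could not be read from dissociated cells, and no biological explanation was tested.

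The KRT5 and ESR1 contrasts were also refitted with the classes swapped in some libraries, which gives 8 splits of the 4 libraries. For genes, the real KRT5 and ESR1 splits called 0 and the highest other split 0, so all 8 splits called as many in each contrast, which a real count of 0 fixes in advance and which decides nothing. Among human-profile cells the real ESR1 split called 3 genes and the highest other 14. In 20 random splits of KRT5-negative cells, where no KRT5 difference exists, 0 to 7 genes were called. For lists, the real KRT5 split called 7 and the highest other 13, and 7 of the 8 splits called at least as many. The real ESR1 split called 2 lists and the highest other 11, and all 8 called at least as many. With 8 splits a share under 0.05 cannot be reached. Why swapped splits called more lists was not tested. The hypoxia list had its lowest median, -0.45, in the real split, and the next in size was -0.33. Since the medians of all 4 libraries were negative, swapping any of them shrinks the fitted median, so this order decides nothing. All 24 genes also went 1 way, and camera called the list, in the swapped splits with medians of -0.33, -0.32, -0.19 and 0.17.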
